A study of Bos taurus with 64 samples.

How the data were processed

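Liver biopsies of 16 beef cows, each taken on 4 days around calving, were measured on 64 one-colour (Cy3) Agilent arrays with probes of 60 bases. Per the labels, each cow belonged to a herbage allowance, a genotype and a replicate number. Each slide of 4 arrays held 1 cow, and each sampling day lay at 1 array position, so day and position coincide. Each of 4 scan days, read from the file headers, held the 4 slides of 1 replicate number, that is 1 cow of each treatment. The time comparisons are within cows and slides, and comparisons between cows set n at 16 cows, not 64 arrays. The cows are separate animals by their labels, and the numbers of cows and arrays limit the precision.

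The deposited scanner files hold the intensity of each spot. Per the file headers, the scanner software (Agilent Feature Extraction) subtracted the background and removed spatial and multiplicative trends within each array, with no scaling between arrays. The submitters' processing notes name version 9.1 of that software, while the file headers name a later one, and which applies is left open. Per the file headers, 16 arrays, those of replicate 2 of every treatment and day, were extracted with a protocol that replaces signals near background by surrogates, and the other 48 without it. The authors' deposited value table holds log2 intensity. Its columns had medians of 6.64 to 9.53 and equalled log2 of the processed signal without scaling or centring (tolerance 0.0001). Of its 64 columns 52 equalled their own scanner file and 12, those of replicate 4 of 3 treatments, equalled the file of another cow. The scanner files were followed, and the deposited assignment was tried as an alternative. Which record is right is not known.

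Here log2 of the processed signal over the 75th percentile of its array was used, with a floor of 0.01 of that percentile (log2 of -6.64). Of 45220 spots per array, 43803 were not controls, with 43653 distinct probes. Outlier spots (0.122% of values) were left out, and 20.6% of values lay at the floor. Probes were kept where well above background on at least 16 of 64 arrays. Spots of 1 probe were averaged, and each gene was represented by its brightest probe, which left 33243 features, 10705 of them with a gene name. Names came from the reference by accessions (7121 probes), gene numbers (7261), current symbols (221) or older symbols (65), while 81 kept the symbol of the file. Another 28904 had no gene name. Of 173 pairs of further probe and comparison 46 had the opposite sign from the brightest, 0 of them with both past the threshold. Where the brightest probe passed, 17 of 48 pairs passed in the same direction. Of 369 genes that the rule names 20 were well above background on fewer than 32 of 64 arrays, so the floor in part sets their differences. No genome was used here, so no coordinates are given. No probe is reported as a bound.

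Tests were made in R 4.3.3 with limma 3.58.1 (lmFit, eBayes) and data.table (version 1.17.8), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Time comparisons used a fixed block for the cow and terms for treatment by time. Comparisons between cows used the mean of each cow over its biopsies, or the value of 1 day, with herbage allowance, genotype class and their interaction, or the 4 genotypes. Gene lists (37, of which 11 hold cell type markers) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Mean list scores were compared with two-sided exact permutation tests that shuffle allowance within genotype class (4900 assignments). Correlations used permutation tests. The lists, the models, the alternatives and the rule for named genes were fixed before the data were examined, except the alternatives stated otherwise.

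The rule named, per comparison, the 10 largest rises and 10 largest falls with a gene symbol among features past the threshold that moved the same way in at least 12 of 16 cows, or 5 and 5 for daily, interaction and breed comparisons. Where fewer than 10 passed, it named the 10 of smallest p. It also named up to 4 members per list by largest change and 30 metabolic genes whatever their p, of which 26 were measured. The text gives fewer list members than the rule allows, and gives the metabolic genes of comparisons between cows mostly as a range. Interactions with time have no direction, so their genes are named only. Some genes that the rule names are not reported here. The genes and lists drawn in the plots were chosen after the results had been seen.

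The steps were tested on simulated data with the spread of the real arrays over 33243 features. For days -15 and -165, changes of log2 0.5, 1, 2 and 3 given to 50 genes each were called in 8, 31, 50 and 50, and 14 unchanged genes were called. For HI against LO cows these were 2, 26, 44 and 49, with 5 unchanged genes called. Of 37 lists only the 1 shifted was called, with correlated genes untested. Alternatives were normexp background correction (offset 50), quantile normalization, no filter on dim probes, a minimum of 60 arrays, every probe on its own, the mean of a gene's probes, the deposited values, other blocks and each cow left out in turn. Added after the data had been seen were a floor of 0.03, outlier spots kept, the deposited slide assignment, and leaving out the 3 cows of conflicting records, the 4 cows of the other protocol or the 2 arrays of lowest correlation, alone or with the scan day as a block. The time comparisons were also made without the 4 cows of each scan day in turn, added likewise.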

Results

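Liver transcript levels were measured in 16 multiparous beef cows followed from gestation into early lactation. The cows grazed native pasture at a herbage allowance of 4 (HI) or 2.5 (LO) kg of dry matter per kg of body weight, as an annual mean. They were purebred Angus (AA) or Hereford (HH) cows (PU), or first crosses between these breeds, AH and HA (CR). Each combination of allowance and genotype class, such as LO-PU, held 4 cows, numbered here as replicates. Every cow was biopsied at 4 times, on days -165 and -15 (gestation) and +15 and +60 (early lactation) from calving. The 64 one-colour arrays had 48.3 to 83.3% of their probes well above background (median 74.8%). Their 75th percentile signal was 559 to 1803 (median 1201). The numbers of cows and of arrays limit the precision. Changes are log2 differences ± SE over 16 cows unless another n is stated, with limma adjusted p values (Benjamini-Hochberg over 33243 features).

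The first question was how the liver changed between days -165 and -15 of gestation. CYP7A1, the rate-limiting enzyme of bile acid synthesis, rose by 2.05 ± 0.36 (adjusted p = 1.79e-04, higher in 15 of 16 cows). HAL, the enzyme that starts histidine breakdown, rose by 2.21 ± 0.22, and S100G, a calcium-binding protein, rose by 2.48 ± 0.25. PCK1, a key gluconeogenic enzyme, rose by 1.26 ± 0.19 (adjusted p = 1.66e-05, higher in 16 of 16 cows). IGF1, the growth factor secreted by the liver under growth hormone, fell by 1.27 ± 0.21 (adjusted p = 1.01e-04, lower in 16 of 16 cows) at its brightest probe, while its other probe gave -0.32 (adjusted p = 0.585). Its binding proteins IGFBP1 (1.44 ± 0.38) and IGFBP2 (1.14 ± 0.23) rose.

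Many genes of fuel metabolism rose in this interval. Of 29 measured genes of fatty acid oxidation and ketogenesis, 15 rose and 0 fell (20 and 0 adjusted over the list alone). Among them were ANGPTL4, an inhibitor of lipoprotein lipase (1.56 ± 0.27), the peroxisomal enzyme EHHADH (1.5 ± 0.33) and the fatty acid hydroxylase CYP4A11 (1.27 ± 0.29), whose other probe gave 0.091 (adjusted p = 0.704). By camera, fatty acid oxidation and ketogenesis lay above the other genes (adjusted p = 6.00e-12, and adjusted p = 0.192 with an estimated correlation). Of 21 gluconeogenic genes, 11 rose and 0 fell (14 and 1 adjusted over the list alone), including FBP1 (0.93 ± 0.20) and pyruvate carboxylase, PC (0.68 ± 0.17). Camera placed gluconeogenesis above the other genes at adjusted p = 2.09e-08, with adjusted p = 0.192 with an estimated correlation. In the urea cycle and amino acid catabolism list 13 of 33 genes rose and 0 fell (15 and 0 adjusted over the list alone), such as GLS2 (1.21 ± 0.20), ARG1 (1.19 ± 0.20) and BHMT (1.07 ± 0.24). By camera, urea cycle and amino acid catabolism lay above the other genes (adjusted p = 1.30e-09, and adjusted p = 0.192 with an estimated correlation). Beside CYP7A1, the bile acid genes CYP27A1 (0.91 ± 0.13) and ACOX2 (0.88 ± 0.13) rose and the bile acid receptor NR1H4 (-0.84 ± 0.17) fell. In that list 5 and 2 of 14 rose and fell (6 and 2 adjusted over the list alone). Camera placed bile acid synthesis and transport above the other genes at adjusted p = 0.00636, with adjusted p = 0.242 with an estimated correlation. The apolipoproteins APOA4 (1.66 ± 0.38) and APOA5 (1.08 ± 0.24) were among 7 of 21 lipoprotein genes that rose, with 0 that fell (9 and 0 adjusted over the list alone). By camera, lipoprotein assembly and transport lay above the other genes (adjusted p = 1.38e-05, and adjusted p = 0.242 with an estimated correlation). Of 24 xenobiotic metabolism genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), led by the glutathione transferase GSTA4 (1.14 ± 0.13). Camera placed xenobiotic metabolism above the other genes at adjusted p = 5.91e-06, with adjusted p = 0.22 with an estimated correlation. Cholesterol synthesis (20 genes, median 0.13) and fatty acid and triglyceride synthesis (19 genes, median 0.13) had 0 members past the threshold.

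Many genes of protein folding fell over the same interval. In the unfolded protein response list 18 of 22 genes fell and 0 rose (21 and 0 adjusted over the list alone). They included the chaperone cofactor DNAJB11 (-1.73 ± 0.28) and the stress-induced proteins MANF (-1.65 ± 0.23) and CRELD2 (-1.39 ± 0.27). By camera, unfolded protein response lay below the other genes (adjusted p = 7.41e-20, and adjusted p = 0.147 with an estimated correlation). SDF2L1 fell by 1.86 ± 0.25 at its brightest probe, while its other probe gave 0.21 (adjusted p = 0.468). Heat shock protein genes fell in 8 of 18 cases (12 adjusted over the list alone), such as DNAJA1 (-0.90 ± 0.26) and CRYAB (-0.88 ± 0.19). Camera placed heat shock proteins below the other genes at adjusted p = 1.94e-06, with adjusted p = 0.202 with an estimated correlation. Of 38 proteasome genes 8 fell, for example PSMD12 (-0.65 ± 0.17), and the interferon-inducible subunit PSMB9 (0.76 ± 0.22) rose. Adjusted over the list alone 17 fell and 3 rose. By camera, proteasome lay below the other genes (adjusted p = 2.95e-06, and adjusted p = 0.242 with an estimated correlation). Mitochondrial ribosomal protein genes fell in 7 and rose in 1 of 74 cases, also adjusted over the list alone. Camera placed mitochondrial ribosomal proteins below the other genes at adjusted p = 0.0110, with adjusted p = 0.697 with an estimated correlation.

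Cell cycle and immune genes moved as well. RRM2, a subunit of ribonucleotide reductase (1.70 ± 0.34), and UBE2C, which acts in mitotic exit (1.60 ± 0.35), were among 18 of 32 cell cycle genes that rose. None of that list fell, and 23 rose adjusted over the list alone. By camera, cell cycle lay above the other genes (adjusted p = 1.78e-12, and adjusted p = 0.192 with an estimated correlation). BUB1 (1.62 ± 0.39) was well above background on 5 arrays of day -165 and 11 of day -15. MHC genes rose in 4 of 14 cases (5 adjusted over the list alone), such as BOLA-DMA (0.99 ± 0.23). Camera placed MHC class I and II above the other genes at adjusted p = 1.94e-06, with adjusted p = 0.192 with an estimated correlation. Of 35 interferon response genes 3 rose and 0 fell, also adjusted over the list alone, led by the chemokine CXCL10 (1.21 ± 0.33). By camera, interferon response lay above the other genes (adjusted p = 7.17e-05, and adjusted p = 0.517 with an estimated correlation). Over the same interval the mean of T and NK cell markers changed by 0.42 ± 0.13, of macrophage and monocyte markers by 0.27 ± 0.12, of hepatocyte markers by 0.19 ± 0.052 and of neutrophil markers by -0.33 ± 0.11. Of 21 T and NK cell markers 7 rose, such as GZMB (0.81 ± 0.19), and 9 did adjusted over the list alone. Camera placed T and NK cell markers above the other genes at adjusted p = 1.49e-06, with adjusted p = 0.192 with an estimated correlation. The neutrophil genes S100A9 (-1.71 ± 0.43) and S100A8 (-1.5 ± 0.37) fell, 4 of 15 in their list and as many adjusted over the list alone (camera adjusted p = 0.115). The eosinophil attractants CCL24 (-2.46 ± 0.49) and CCL26 (-1.66 ± 0.45) and the activin subunit INHBA (-2.35 ± 0.28) fell.

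A further 6 lists lay above the other genes by camera. For macrophage and monocyte markers, 4 rose and 0 fell of 17 (8 and 0 adjusted over the list alone), with adjusted p = 9.97e-05, and adjusted p = 0.306 with an estimated correlation. For hepatocyte markers, 3 rose and 0 fell of 16 (3 and 1 adjusted over the list alone), with adjusted p = 0.00764, and adjusted p = 0.337 with an estimated correlation. For adipocyte markers, 4 rose and 0 fell of 14 (4 and 0 adjusted over the list alone), with adjusted p = 0.00354, and adjusted p = 0.202 with an estimated correlation. For extracellular matrix and stellate cells, 3 rose and 0 fell of 25 (3 and 0 adjusted over the list alone), with adjusted p = 0.00846, and adjusted p = 0.337 with an estimated correlation. For negative acute phase and major plasma proteins, 2 rose and 0 fell of 15 (2 and 0 adjusted over the list alone), with adjusted p = 0.00987, and adjusted p = 0.535 with an estimated correlation. For complement and coagulation, 3 rose and 0 fell of 28 (3 and 1 adjusted over the list alone), with adjusted p = 0.0488, and adjusted p = 0.692 with an estimated correlation. Examples were the Kupffer cell gene CD5L (0.44 ± 0.10), APOA1 (0.56 ± 0.19), the lipase PNPLA2 (0.73 ± 0.12), the vitamin A esterifying enzyme LRAT (0.98 ± 0.16), KNG1 (0.47 ± 0.12) and C4BPB (0.50 ± 0.11). The other probes of CD5L and KNG1 gave 0.18 and 0.21, both short of the threshold. Lists not called by camera also held genes past the threshold. The signalling subunit PIK3R1 (-1.11 ± 0.16), the iron hormone HAMP (-1.44 ± 0.33), APCS (-0.67 ± 0.17), KLF4 (-1.25 ± 0.25) and GADD45B (-1.38 ± 0.32) fell, and the prolactin receptor PRLR (1.08 ± 0.25) rose. The numbers that rose and fell were 0 and 2 of 22 for acute phase proteins, 3 and 2 of 15 for circadian clock, 0 and 2 of 17 for immediate early genes and 3 and 4 of 23 for somatotropic axis and insulin signalling. They were 1 and 3 of 26 for oxidative stress defence, 1 and 2 of 85 for oxidative phosphorylation, 1 and 1 of 78 for cytosolic ribosomal proteins, 2 and 0 of 20 for steroid, retinoid and thyroid handling and 1 and 0 of 14 for endothelial cell markers. Adjusted over the list alone these pairs were, in order, 0 and 3, 3 and 4, 0 and 4, 3 and 4, 1 and 3, 0 and 1, 1 and 0, 3 and 0 and 1 and 0. Erythroid, B and plasma cell, cholangiocyte, skeletal muscle and skin and other epithelium markers had 0 past the threshold.

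In total 3343 features changed between days -165 and -15, 1713 upward and 1630 downward, and 1473 of them carried a gene name. The 10 largest rises seen in at least 12 cows were those of USH1C (2.82 ± 0.31), S100G, HAL, CYP7A1, KRT78 (2.0 ± 0.54), ECEL1 (1.95 ± 0.38), CLDN15 (1.93 ± 0.29), HHIPL2 (1.92 ± 0.40), DYNC1I1 (1.87 ± 0.24) and ERICH2 (1.84 ± 0.17). The 10 largest falls were those of CCL24, AK4 (-2.42 ± 0.36), INHBA, STEAP4 (-2.24 ± 0.30), RNF125 (-2.13 ± 0.37), FUT1 (-2.03 ± 0.44), SDF2L1, DNAJB11, S100A9 and CCL26. FUT1 was well above background on 38 of 64 arrays, and its other probe gave -0.71 (adjusted p = 0.244). Of the 26 measured genes chosen beforehand for their role in liver metabolism 9 passed, among them PPARGC1A (0.71 ± 0.16) beside CYP7A1, PCK1, PC, ANGPTL4, IGFBP1, IGFBP2 and IGF1. The others included GHR (-0.29 ± 0.18), SCD (-0.11 ± 0.33) and PPARA (-0.50 ± 0.26). A further 13, ALB, APOB, CPS1, FASN, HP, IGFALS, IGFBP3, INSIG1, MTTP, SAA3, SOCS2, SREBF1 and TAT, had adjusted p = 0.197 to 0.989. Analysed by scan day (4 cows each) there were 11, 3165, 1384 and 0 genes within scan days 1, 2, 3 and 4. Of the features called without scan days 1, 2, 3 and 4 in turn (2796, 1021, 596 and 4605), 77.9, 85.1, 97.8 and 85.8% had the same direction in the scan day left out. The count was 1470 without the cow as a block and 1021 (691 higher and 330 lower) without the 4 cows whose arrays had another extraction protocol. It was 2065 without HI-CR replicate 2, 2002 without HI-PU replicate 2, 2070 without LO-CR replicate 2 and 2194 without LO-CR replicate 3, and the deposited values gave 650 higher and 1050 lower. Day and array position coincided on every slide, and 8 spike-in transcripts differed by a mean of 0.28 between the positions of days -15 and -165.

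**Figure D1:**
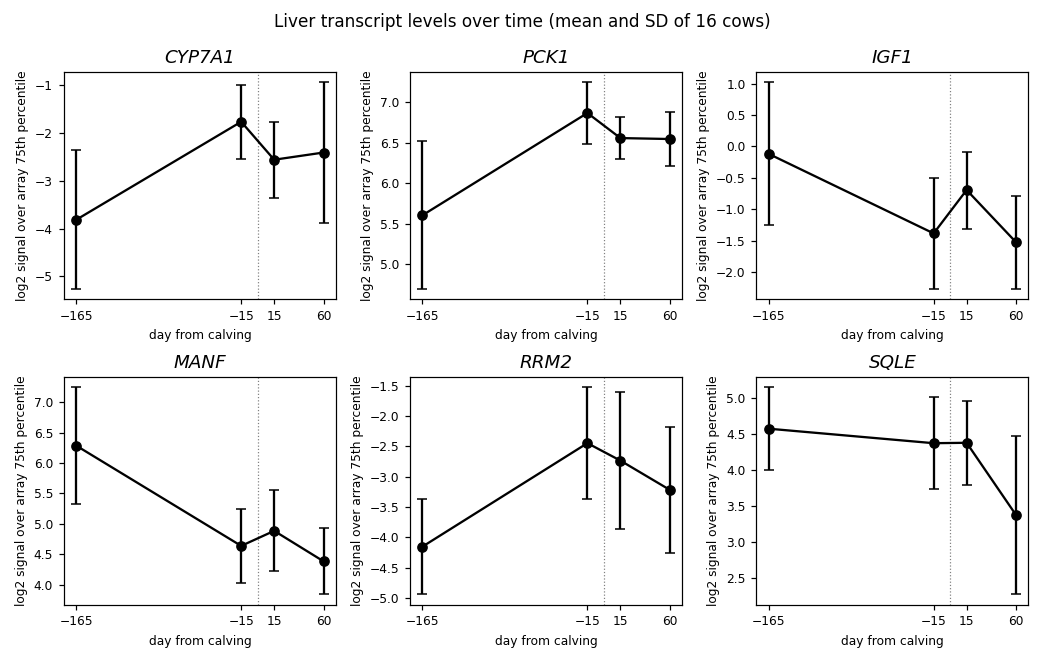
Level of 6 liver transcripts (log2 of signal over the 75th percentile of the array, vertical axis) by day from calving (horizontal axis), as mean and SD of 16 cows, with a dotted line at calving. At the brightest probe of each, CYP7A1, PCK1 and RRM2 rose and IGF1 and MANF fell between days -165 and -15, and SQLE fell by 1.0 ± 0.21 between days +15 and +60.

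Across calving, between days -15 and +15, few transcripts passed the threshold. WNT2, a secreted signalling protein, rose by 1.02 ± 0.16 (adjusted p = 0.00240, higher in 15 of 16 cows). ADAMTS1, an extracellular matrix protease, rose by 0.70 ± 0.14 (adjusted p = 0.0418, 13 of 16 cows). ADIPOR2, an adiponectin receptor, fell by 1.07 ± 0.21 (adjusted p = 0.0418, 15 of 16 cows). In all 8 features changed, 4 upward and 4 downward, the 5 others having no gene symbol, and 3793 had an unadjusted p under 0.05, where chance gives 1662. The next smallest p belonged to the mitochondrial carrier SLC25A47 (-1.1 ± 0.23, adjusted p = 0.0605). Then followed SLC25A30 (-1.08 ± 0.23), the transporters SLC47A1 (-1.27 ± 0.27) and MFSD2A (-1.18 ± 0.26), KRT78 (-2.53 ± 0.54), DTX1 (-1.11 ± 0.24) and LAYN (0.62 ± 0.13), each with adjusted p = 0.0647. None of the 26 metabolic genes passed, with ANGPTL4 at -1.21 ± 0.27 (adjusted p = 0.0647), SCD at 1.12 ± 0.33 and IGF1 at 0.69 ± 0.21, whose other probe gave -0.057 (adjusted p = 0.960).

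Camera called 9 lists across calving, although 0 of their genes passed among all features, and each had adjusted p = 0.896 with an estimated correlation. Below the other genes were, with medians and adjusted p, fatty acid oxidation and ketogenesis (median -0.20, 0.00308), gluconeogenesis (median -0.19, 0.0154), urea cycle and amino acid catabolism (median -0.13, 0.0101) and complement and coagulation (median -0.14, 0.0197). Above them were endothelial cell markers (median 0.10, 0.00338), heat shock proteins (median 0.16, 0.00761), proteasome (median 0.067, 0.00761), oxidative phosphorylation (median 0.045, 0.00308) and unfolded protein response (median 0.13, 0.0215). Adjusted over the list alone, 2 of 29 genes of fatty acid oxidation passed downward and 2 of 23 somatotropic genes upward. The fatty acid synthesis, heat shock and endothelial lists had 1 each upward. Without HI-CR replicate 4 the number of called lists was 4. Scan days gave 1822, 0, 0 and 0 genes within scan days 1, 2, 3 and 4, and 0, 5, 1 and 6 features passed without scan days 1, 2, 3 and 4 in turn. The count of 8 was 3 without HI-CR replicate 1, 4 without HI-PU replicate 1, 3 without LO-CR replicate 1, 3 without LO-PU replicate 1, 34 without LO-CR replicate 2, 3 without LO-PU replicate 2, 16 without HI-CR replicate 3, 3 without HI-PU replicate 3, 3 without LO-CR replicate 3, 3 without LO-PU replicate 3, 5 without HI-CR replicate 4, 4 without LO-CR replicate 4 and 27 without LO-PU replicate 4. It was 4 without the cow as a block, 15 with the cow as a random block and 24 with 3 cows assigned as in the deposited values. The split was 2 higher and 0 lower with normexp background correction and 7 higher and 3 lower with a higher floor.

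Between days +15 and +60 of lactation, genes of sterol and fatty acid synthesis were among those that fell. SCD, the desaturase of monounsaturated fatty acid synthesis, fell by 1.82 ± 0.33 (adjusted p = 0.00283, lower in 13 of 16 cows). Of 20 cholesterol synthesis genes 8 fell and 0 rose (18 and 0 adjusted over the list alone). Among them were squalene epoxidase, SQLE (-1.0 ± 0.21), HMGCS1, which makes the precursor of mevalonate (-1.16 ± 0.29), FDPS (-0.85 ± 0.19) and MSMO1 (-0.80 ± 0.15). The list median was -0.66. Camera gave adjusted p = 4.40e-23, and adjusted p = 0.0314 with an estimated correlation, the only list of this interval called both ways. In the fatty acid and triglyceride list 3 of 19 genes fell, SCD, the acetyl-CoA synthetase ACSS2 (-1.49 ± 0.32) and the desaturase FADS2 (-1.35 ± 0.31), and 4 did adjusted over the list alone. By camera, fatty acid and triglyceride synthesis lay below the other genes (adjusted p = 1.82e-04, and adjusted p = 0.348 with an estimated correlation). IGF1 fell by 0.83 ± 0.21 (adjusted p = 0.0431, lower in 15 of 16 cows), and its other probe gave -0.95 (adjusted p = 0.148). It and SCD were the 2 of 26 metabolic genes to pass, while INSIG1 gave -0.67 ± 0.21 and IGFALS -0.66 ± 0.18 (adjusted p = 0.0704).

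The other 14 lists called by camera in this interval also lay below the other genes, and 0 of them passed with an estimated correlation. Their medians, adjusted p with the preset and adjusted p with an estimated correlation follow. The first were heat shock proteins (median -0.32, adjusted p = 3.04e-06, 0.417), oxidative phosphorylation (median -0.10, adjusted p = 4.13e-07, 0.671), negative acute phase and major plasma proteins (median -0.16, adjusted p = 1.82e-04, 0.590) and oxidative stress defence (median -0.19, adjusted p = 6.11e-04, 0.480). Then came steroid, retinoid and thyroid handling (median -0.15, adjusted p = 6.18e-04, 0.348), xenobiotic metabolism (median -0.15, adjusted p = 0.00115, 0.671) and unfolded protein response (median -0.22, adjusted p = 0.00249, 0.715). Next were macrophage and monocyte markers (median -0.15, adjusted p = 0.00252, 0.689), proteasome (median -0.078, adjusted p = 0.0124, 0.715), mitochondrial ribosomal proteins (median -0.068, adjusted p = 0.0124, 0.715) and immediate early genes (median -0.19, adjusted p = 0.0124, 0.689). The last were cell cycle (median -0.10, adjusted p = 0.0271, 0.715), extracellular matrix and stellate cells (median -0.10, adjusted p = 0.0456, 0.715) and acute phase proteins (median -0.10, adjusted p = 0.0494, 0.715). The respiratory chain genes NDUFA5 (-1.13 ± 0.19), ATP5PO (-0.72 ± 0.18) and UQCRH (-0.51 ± 0.13) fell, 3 of 85 in their list (6 adjusted over the list alone), while the other probe of NDUFA5 gave -0.10 (adjusted p = 0.862). The corticosteroid-binding globulin SERPINA6 (-1.09 ± 0.23), thioredoxin TXN (-0.59 ± 0.15) and AOX1 (-0.61 ± 0.13) fell, 1 each in the plasma protein, oxidative stress and xenobiotic lists (2, 2 and 3 adjusted over the list alone). Adjusted over the list alone, 2 steroid, retinoid and thyroid genes and 1 each of the heat shock and cell cycle lists passed downward, and 1 oxidative stress gene upward. The B cell receptor gene CD79A (-1.86 ± 0.46), hormone-sensitive lipase LIPE (-0.89 ± 0.22) and the ribosomal proteins RPS12 (-0.96 ± 0.21) and RPS29 (-0.56 ± 0.12) fell too. Complement factor CFB fell by 0.62 ± 0.15, and gave 0.0094 with normexp background correction, while its other probe gave -0.0073 (adjusted p = 0.986).

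In total 286 features changed between days +15 and +60, 66 upward and 220 downward. The largest falls were those of GPR37L1 (-2.77 ± 0.34), CD79A, CRELD1 (-1.84 ± 0.25), SCD, ZDHHC24 (-1.67 ± 0.30), ACSS2, OLIG3 (-1.47 ± 0.29), PAPPA2 (-1.45 ± 0.37), ME3 (-1.45 ± 0.31) and PPP1R7 (-1.39 ± 0.27), whose other probe gave -0.36 (adjusted p = 0.666). The largest rises were those of H2AC10 (1.21 ± 0.24), TLX2 (1.13 ± 0.25), HTR3A (1.11 ± 0.28), PRSS1 (0.96 ± 0.23) and NEURL2 (0.95 ± 0.23). Then came WNT6 (0.92 ± 0.18), KIR3DL2 (0.91 ± 0.21), PRDM12 (0.90 ± 0.20), REP15 (0.88 ± 0.17) and LIM2 (0.87 ± 0.22). H2AC10 was well above background on 3 arrays of day +15 and 14 of day +60. Scan days gave 0, 0, 3 and 1 genes within scan days 1, 2, 3 and 4. Called without each scan day in turn there were 182, 112, 7 and 151 features, of which 78.6, 88.4, 100 and 92.1% had the same direction in the scan day left out. The count was 51 without the cow as a block and 178 without HI-CR replicate 1, 445 without HI-PU replicate 1, 178 without LO-CR replicate 1, 163 without LO-CR replicate 2, 167 without HI-CR replicate 3, 151 without LO-CR replicate 3, 138 without LO-PU replicate 3 and 151 without LO-PU replicate 4. The split was 6 higher and 140 lower with normexp background correction, 3 higher and 208 lower with the deposited values, 7 higher and 105 lower without the 4 cows of the other protocol, and 216 higher and 262 lower without the 2 arrays that correlated least with the others, HI-PU replicate 4 at day +60 and LO-PU replicate 2 at day -15.

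**Figure D2:**
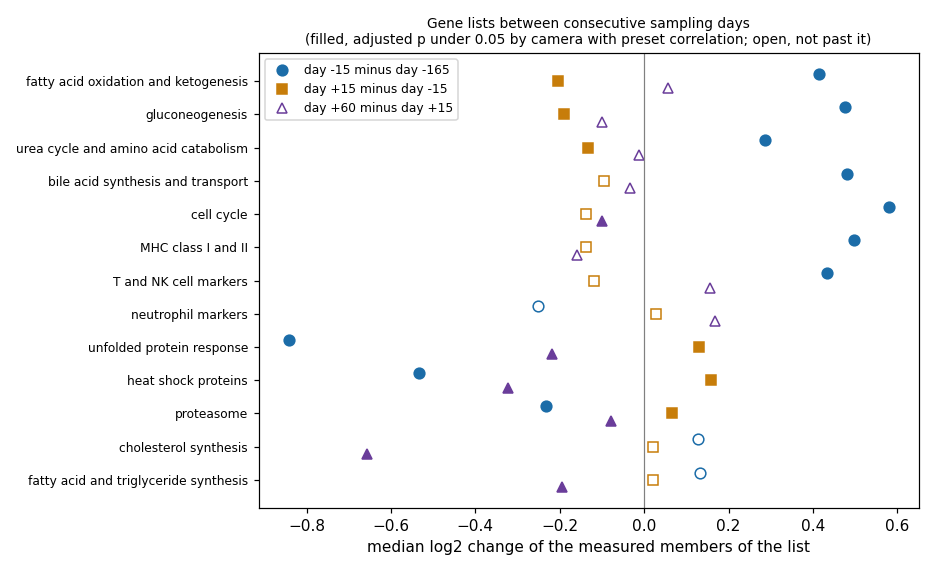
Median log2 change of the measured members (horizontal axis) of 13 gene lists (vertical axis) between consecutive sampling days, over 16 cows, with symbols filled where camera with a preset correlation passed. With an estimated correlation, of these lists only cholesterol synthesis between days +15 and +60 (median -0.66) passed.

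In early lactation (days +15 and +60) relative to gestation (days -165 and -15), some folding and acute phase genes fell and some interferon genes rose. In the unfolded protein response list 13 of 22 genes fell and 0 rose (14 and 0 adjusted over the list alone), among them CRELD2 (-0.97 ± 0.19), DNAJB11 (-0.90 ± 0.20), MANF (-0.83 ± 0.16) and HERPUD1 (-0.78 ± 0.16). Camera placed unfolded protein response below the other genes at adjusted p = 4.10e-07, with adjusted p = 0.983 with an estimated correlation. The protease inhibitor A2M (-0.83 ± 0.16) and the cytokine signal transducer STAT3 (-0.60 ± 0.19) were among 5 of 22 acute phase genes that fell, while 1 rose (1 and 6 adjusted over the list alone upward and downward). By camera, acute phase proteins lay below the other genes (adjusted p = 0.0359, and adjusted p = 0.983 with an estimated correlation). Of 35 interferon response genes 5 rose, also adjusted over the list alone, including XAF1 (0.56 ± 0.17), ZBP1 (0.51 ± 0.16) and IRF1 (0.39 ± 0.11). Camera placed interferon response above the other genes at adjusted p = 1.45e-04, with adjusted p = 0.983 with an estimated correlation. The folding and interferon lists had medians of -0.84 and 0.36 between days -165 and -15, but 0.13 and 0.072 across calving, so day -15 was already near lactation. The T cell genes CD8A (0.52 ± 0.12) and CD3D (0.42 ± 0.14) rose beside them, 4 of 21 markers (5 adjusted over the list alone), while the other probe of CD3D gave 0.18 (adjusted p = 0.637). By camera, T and NK cell markers lay above the other genes (adjusted p = 0.00582, and adjusted p = 0.983 with an estimated correlation). The growth hormone receptor GHR fell by 0.45 ± 0.13 (adjusted p = 0.0138, 13 of 16 cows), and SOCS2, an inhibitor of its signalling, rose by 0.63 ± 0.17 (adjusted p = 0.00893, 11 of 16 cows). With INSIG1 (-0.45 ± 0.15) these were the 3 of 26 metabolic genes to pass at their brightest probe. IGF1 gave -0.36 ± 0.15 (adjusted p = 0.0946), but its other probe passed at -0.69 (adjusted p = 0.0293). So did the other probe of IGFALS at -0.65 (adjusted p = 0.0161), where the brightest gave -0.13.

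The other lists called here had adjusted p = 0.983 with an estimated correlation. They were, with medians and adjusted p, cholesterol synthesis (median -0.27, 0.0359), heat shock proteins (median -0.26, 0.0353), cell cycle (median 0.12, 0.0359), endothelial cell markers (median 0.11, 0.0359) and skeletal muscle markers (median 0.79, 0.0359). Of 20 cholesterol synthesis genes 3 fell (5 adjusted over the list alone), such as CYP51A1 (-0.60 ± 0.13). Of 18 heat shock genes 4 fell, such as DNAJA1 (-0.56 ± 0.18), with as many adjusted over the list alone. In the cell cycle list 4 rose and 1 fell (5 and 1 adjusted over the list alone), and 2 endothelial markers rose, also adjusted over the list alone. Skeletal muscle markers had 0 of 12 past the threshold. The muscle gene MYBPC1, the largest rise (1.45 ± 0.42), was well above background on 23 of 64 arrays. In total 5187 features changed, 1955 upward and 3232 downward. Other large rises were those of CDON (1.30 ± 0.21), IL20RA (1.17 ± 0.16), S100G (1.17 ± 0.18), DYNC1I1 (1.14 ± 0.17) and PRAP1 (1.09 ± 0.25), and of HHIPL2 (1.07 ± 0.28), SLC25A40 (1.02 ± 0.27), EXOC3L4 (1.01 ± 0.21) and GRB7 (1.0 ± 0.18). The largest falls were those of KRT78 (-1.87 ± 0.38), GPR37L1 (-1.79 ± 0.24), CCL24 (-1.76 ± 0.34), CCL26 (-1.74 ± 0.32) and NOL10 (-1.66 ± 0.19), and of ZDHHC24 (-1.52 ± 0.21), PTX3 (-1.51 ± 0.30), CRELD1 (-1.5 ± 0.17), INHBE (-1.39 ± 0.27) and egr1 (-1.38 ± 0.36). Scan days gave 4478, 779, 23 and 0 genes within scan days 1, 2, 3 and 4. Without each in turn 2030, 3500, 2793 and 4380 features were called, and 91, 80.1, 92.3 and 73.8% of these had the same direction in the scan day left out. The count was 2191 without the cow as a block, and the deposited values gave 466 higher and 2811 lower. Without the 3 cows of conflicting records it was 1963 higher and 1825 lower. Camera called 9 lists, 4 without HI-PU replicate 2 or LO-CR replicate 2, 5 without LO-CR replicate 3 and 3 without LO-PU replicate 3. It called 3 with quantile normalization and 5 without the 4 cows of the other protocol.

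Herbage allowance was tested on each cow's mean over its 4 biopsies (8 HI and 8 LO cows). No feature passed the threshold in limma, and 646 had an unadjusted p under 0.05, fewer than the 1662 that chance gives. Several genes of smallest p belong to skeletal muscle. Troponin T, TNNT1, differed by 2.03 ± 0.46 (HI minus LO), skeletal actin, ACTA1, by 1.86 ± 0.55 and the muscle protein SMPX by 1.51 ± 0.42, each with adjusted p = 1.00. TNNT1 was well above background on 15 HI and 10 LO arrays and SMPX on 12 and 6 (of 32 each). Muscle transcripts stood high in single biopsies of both allowances. The mean score of 12 muscle markers was 0.65 ± 0.99 in HI and -0.65 ± 0.70 in LO cows (SD, n = 8 each, exact permutation p = 0.0114, and 0.423 adjusted over 37 lists). Their median difference was 1.45, and 9 passed adjusted over the list alone. Camera placed skeletal muscle markers above the other genes at adjusted p = 9.51e-30, with adjusted p = 0.0276 with an estimated correlation. The fry adjusted p was 0.482. Among the 26 metabolic genes IGF1 differed by 0.66 ± 0.27, IGFBP2 by -0.49 ± 0.14 and SCD by -0.55 ± 0.26, each short of the threshold. The remaining genes of smallest p were RBFOX1 (0.75 ± 0.22), SLC16A8 (-0.95 ± 0.25), C11H2orf50 (-0.88 ± 0.25), DCDC2B (-0.75 ± 0.22), ABCA4 (-0.68 ± 0.18) and ADAMTS10 (-0.56 ± 0.16). SLC16A8, C11H2orf50, DCDC2B and ADAMTS10 had the opposite sign with normexp background correction, under which the median of all features was 0.10 and not -0.072. Other lists called by camera were, with medians and adjusted p, cytosolic ribosomal proteins (median -0.11, 2.10e-04), immediate early genes (median 0.10, 0.00879) and interferon response (median 0.076, 0.0194), each with adjusted p = 0.986 with an estimated correlation. With the scan day as a block 0 features passed (1153 at an unadjusted p under 0.05). The feature count was 2 without LO-PU replicate 1 and 3 without HI-CR replicate 2. The number of called lists was 4, also with that block, but 2 without LO-CR replicate 1, HI-PU replicate 2 or HI-PU replicate 3, 7 without LO-PU replicate 2 and 21 with normexp background correction. Within scan days each allowance had 2 cows, and the differences of all features correlated between scan days at r = -0.11 to 0.067 across genes, which are not independent replicates.

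**Figure D3:**
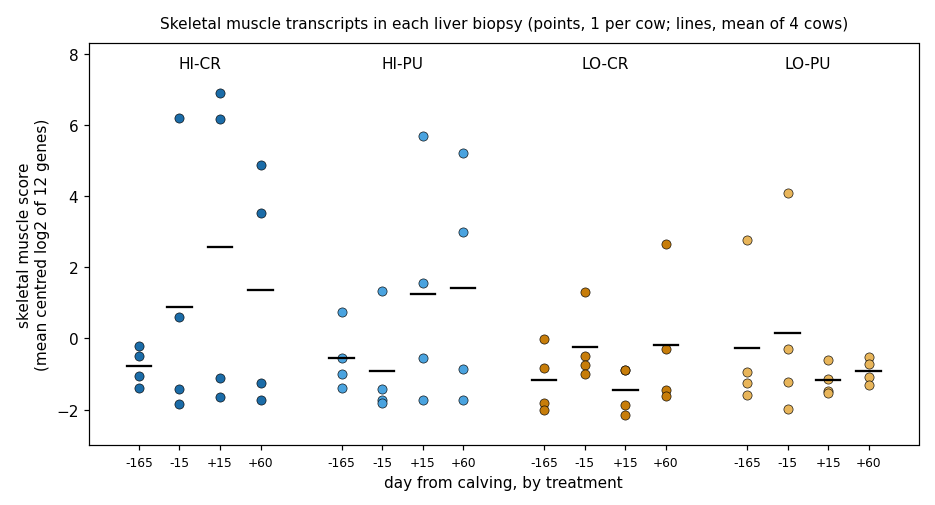
Skeletal muscle score of each liver biopsy (mean of 12 muscle marker genes, each centred on its mean log2 level over 64 arrays, vertical axis) by day from calving and treatment (horizontal axis), with 1 point per cow and lines at the mean of 4 cows. The highest scores, 6.91 and 6.19, were in single HI-CR biopsies of days +15 and -15.

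Crossbred and purebred cows (8 each) were compared in the same way. No feature passed in limma, and 632 had an unadjusted p under 0.05, also fewer than the 1662 that chance gives. With the scan day as a block 0 passed (1524 at an unadjusted p under 0.05). The smallest p values belonged to B4GALNT1 (-0.73 ± 0.20), LY6G6E (-0.78 ± 0.25), ZMIZ2 (-0.63 ± 0.22), SSTR5 (-0.60 ± 0.19) and EYA2 (-0.59 ± 0.21). Next were ABAT (-0.53 ± 0.18), GUCA1A (0.60 ± 0.19), ME3 (0.56 ± 0.19), BMP2 (0.53 ± 0.19) and PPP3CA (0.40 ± 0.14), all with adjusted p = 1.00, and SSTR5 had the opposite sign with normexp background correction. Metabolic genes ran from -0.71 for HP, an acute phase protein that binds haemoglobin, to 0.46 for SOCS2. Lists above the other genes in crossbred cows were, with medians and camera adjusted p, cytosolic ribosomal proteins (median 0.10, 4.32e-07), immediate early genes (median 0.15, 0.00541), mitochondrial ribosomal proteins (median 0.065, 0.00541), unfolded protein response (median 0.11, 0.00652), cholesterol synthesis (median 0.12, 0.0184) and oxidative phosphorylation (median 0.056, 0.0184). Each had adjusted p = 0.966 with an estimated correlation and 0 genes past the threshold, also adjusted over the list alone. The feature count was 2 without LO-PU replicate 1. The number of called lists was 6, also with that block, but 11 without HI-PU replicate 1, 2 without HI-PU replicate 3, 3 without LO-PU replicate 4 and 1 with normexp background correction. It was 3 with quantile normalization and 2 without the 2 arrays of lowest correlation or without the 4 cows of the other protocol. Differences correlated between scan days at r = -0.15 to 0.27 across genes. The interaction of allowance and genotype class also had 0 features past the threshold (1008 at an unadjusted p under 0.05, again below 1662). ZP2 (2.83 ± 0.46, adjusted p = 0.460) had the smallest p, followed by MYO6 (-0.60 ± 0.14), ACKR2 (1.28 ± 0.30), MUC1 (-0.81 ± 0.21) and CNGA2 (0.71 ± 0.19) and then ARFGEF2 (0.98 ± 0.26), SLC47A1 (0.88 ± 0.23), FZD8 (1.33 ± 0.35), IL25 (1.41 ± 0.39) and KCNJ5 (0.77 ± 0.22). The interaction count was 3 without LO-PU replicate 1 and 4 with the cow as a random block.

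Day by day, SCD differed by -1.98 ± 0.47 in HI relative to LO cows at day +60, when the median of all features was -0.15. HI-PU replicate 4 that day had the lowest median correlation with the other arrays (0.804) and 53.3% of its probes well above background. SCD differed by -1.97 without it. The cholesterol synthesis list had a median of -0.67 that day, with 0 of 20 members above 0. By camera, cholesterol synthesis lay below the other genes (adjusted p = 9.03e-17, and adjusted p = 0.128 with an estimated correlation). Interferon response genes had a median of 0.30. Camera placed interferon response above the other genes at adjusted p = 2.60e-13, with adjusted p = 0.498 with an estimated correlation. Muscle markers had a median of 2.17 that day (camera adjusted p = 3.84e-13, and adjusted p = 0.128 with an estimated correlation) and of 3.94 at day +15 (camera adjusted p = 4.15e-20, and adjusted p = 0.203 with an estimated correlation). At day -15 IGF1 differed by 1.13 ± 0.34 and IGFBP1 by -1.28 ± 0.62, and at day -165 T and NK cell markers had a median of -0.44. By camera, T and NK cell markers lay below the other genes (adjusted p = 2.80e-07, and adjusted p = 0.267 with an estimated correlation). In crossbred relative to purebred cows, cholesterol synthesis genes had a median of 0.52 at day +60 and HP differed by -1.40 ± 0.82. Camera placed cholesterol synthesis above the other genes at adjusted p = 1.92e-08, with adjusted p = 0.961 with an estimated correlation. Daily counts of lists called by camera ran from 0 to 11, from 0 to 15 when 1 cow was left out, reached 26 with normexp background correction, and were 0 with an estimated correlation. None of the 8 daily comparisons had a feature past the threshold in limma. At an unadjusted p under 0.05 there were 457, 777, 743 and 731 for allowance and 1076, 821, 399 and 906 for genotype class. Each lay below the 1662 that chance gives. Without LO-PU replicate 1 there were 3 for allowance and 1 for genotype class at day -15, and without HI-CR replicate 2 there was 1 for each at day +15. Tests of whether changes over time differed had 0 features past the threshold. At an unadjusted p under 0.05 they had 577 for allowance and 765 for genotype class, where chance gives 1662. Their genes of smallest p were ANKRD37, HDAC2, HSD17B7, KIAA2012, MSMO1, PTX3, SCD, SCRN1, SFTPD and ZBTB21 for allowance. For genotype class they were DKK3, FMOD, GABRE, HTR3C, JADE3, MAP3K7, RTL1, TAT, THRSP and ZRANB2.

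The genes of smallest p in the daily comparisons were all short of the threshold. For allowance at day -165 they were TAT (0.73 ± 0.22), DDIT4 (0.93 ± 0.28), RSPO1 (1.29 ± 0.40), IQCG (-0.84 ± 0.23) and SLC9B1 (-0.85 ± 0.24). Next were FMNL3 (-0.86 ± 0.25), TRGC6 (-0.93 ± 0.27), RTL1 (-0.76 ± 0.23), ZNF346 (-0.85 ± 0.26) and DCDC2B (-1.28 ± 0.38). At day -15 they were TMEM45B (0.72 ± 0.18), TM7SF2 (0.74 ± 0.20), MID1IP1 (1.26 ± 0.36), XXYLT1 (0.68 ± 0.18) and GNPDA1 (0.79 ± 0.22). Then came FGF12 (0.67 ± 0.19), SLC7A9 (0.70 ± 0.20), ABCA4 (-0.76 ± 0.20), IL1RN (-0.94 ± 0.26) and FOSL2 (-0.98 ± 0.29). On day +15 the muscle gene MYBPC1 (3.74 ± 1.1) stood with H2BC19 (0.63 ± 0.18), STAR (-0.59 ± 0.15), PTX3 (-1.96 ± 0.48) and C11H2orf50 (-1.12 ± 0.29). After these were SMAD5 (-0.86 ± 0.23), SALL1 (-1.26 ± 0.34), IL19 (-0.91 ± 0.26), SGK1 (-0.55 ± 0.16) and CTNND2 (-1.06 ± 0.33). On day +60 SCD stood with SFTPD (-1.49 ± 0.34), PTX3 (-1.02 ± 0.23), LIPE (-1.07 ± 0.25) and C11H2orf50 (-1.21 ± 0.29). They were joined by SERPINE3 (-1.32 ± 0.32), STXBP5L (-0.95 ± 0.23), SP4 (-0.91 ± 0.23) and PDGFC (-1.27 ± 0.34). For genotype class day -165 gave HOMER3 (-0.94 ± 0.21), ABHD1 (-0.63 ± 0.16), AVPR1B (-0.84 ± 0.22), PLEKHG2 (-1.01 ± 0.27) and LY6G6E (-2.06 ± 0.55). It also gave MFGE8 (-1.07 ± 0.29), GPR141 (-0.73 ± 0.21), hmm4226 (-0.78 ± 0.23), PI15 (-0.99 ± 0.30) and ATOSB (0.80 ± 0.25). Day -15 gave EHMT2 (-0.89 ± 0.20), SAXO1 (-1.1 ± 0.29), RARG (-1.01 ± 0.29) and BCHE (-1.17 ± 0.34). Further genes were GTF3C3 (-0.91 ± 0.27), DGKE (-1.36 ± 0.41), LYPD3 (-0.73 ± 0.22), SLC29A3 (-0.48 ± 0.15) and DBNDD1 (-0.76 ± 0.24). Day +15 gave CLEC7A (-1.07 ± 0.27), CYP2C89 (-1.12 ± 0.29), ARL9 (-0.91 ± 0.26), ADAM32 (-0.78 ± 0.24) and GSTA4 (-0.69 ± 0.22). Others that day were KCNK10 (-0.77 ± 0.25), DNAAF11 (-1.17 ± 0.39), SSTR5 (-0.69 ± 0.23), SFRP2 (1.5 ± 0.50) and GUCA1A (0.77 ± 0.26). Day +60 gave HTR3C (1.40 ± 0.37), QTRT2 (1.24 ± 0.33), SLC45A2 (1.26 ± 0.36), IGSF9 (1.42 ± 0.41) and COL8A1 (-0.72 ± 0.21). The rest were PHKG1 (1.25 ± 0.37), LRR1 (-1.11 ± 0.33), RRS1 (1.02 ± 0.31), PRRG3 (0.96 ± 0.29) and SLC22A7 (-0.90 ± 0.27). With normexp background correction the sign turned for C11H2orf50, IL19, SMAD5 and CTNND2 at day +15 and for C11H2orf50, LIPE, PDGFC, PTX3, SP4 and STXBP5L at day +60. It also turned for the day -165 genes AVPR1B, GPR141, hmm4226, HOMER3, LY6G6E, MFGE8, PI15 and PLEKHG2. The median of all features under that correction was 0.15 and 0.10 for allowance at days +15 and +60 (otherwise -0.087 and -0.15) and 0.29 for genotype class at day -165 (otherwise -0.043). DNAAF11 turned with the other slide assignment, and KCNK10 and LYPD3 differed by 0 with a higher floor.

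The labels also gave the breed of each purebred cow and the direction of each cross. IGFLR1, a receptor of the tumour necrosis factor receptor family, was at -3.04 ± 0.37 in AA and 0.64 ± 0.67 in HH cows (SD, n = 4 each). The difference was -3.68 ± 0.33 (adjusted p = 5.24e-04), while AH and HA cows were at 0.86 ± 0.52 and 0.61 ± 0.25 (SD, n = 4 each). LOC540552, named after its values were seen, was higher in AA cows by 4.68 ± 0.67 (adjusted p = 0.0396). The 3 other features past the threshold had only transcript identifiers and differed by 1.55 ± 0.21, 1.07 ± 0.16 and -2.68 ± 0.35. The next smallest p values belonged to OCIAD2 (-1.26 ± 0.21), CHST1 (1.16 ± 0.18), FH (-1.2 ± 0.20), SLC43A3 (1.1 ± 0.18) and ATP6V0D2 (-2.91 ± 0.54). Then came IVNS1ABP (1.02 ± 0.19), PALMD (-0.92 ± 0.17), CDIN1 (-1.30 ± 0.24) and GTPBP10 (-1.35 ± 0.26), these 9 with adjusted p = 0.0705 to 0.0880. Of the metabolic genes CYP7A1 differed by -1.23 ± 0.31 (adjusted p = 0.124) and HP by -1.42 ± 0.64. Camera called 12 lists, and 0 with an estimated correlation, whose adjusted p follows each camera value. Below the other genes in AA cows were complement and coagulation (median -0.26, adjusted p = 1.82e-04, 0.595), oxidative phosphorylation (median -0.25, adjusted p = 3.38e-06, 0.595), mitochondrial ribosomal proteins (median -0.23, adjusted p = 6.58e-05, 0.595) and acute phase proteins (median -0.35, adjusted p = 0.00151, 0.595). So were gluconeogenesis (median -0.21, adjusted p = 0.0115, 0.595), lipoprotein assembly and transport (median -0.25, adjusted p = 0.0162, 0.595) and urea cycle and amino acid catabolism (median -0.18, adjusted p = 0.0179, 0.595). The last were proteasome (median -0.16, adjusted p = 0.0179, 0.728), hepatocyte markers (median -0.19, adjusted p = 0.0341, 0.595) and fatty acid oxidation and ketogenesis (median -0.20, adjusted p = 0.0370, 0.728). Above them were immediate early genes (median 0.42, adjusted p = 0.00233, 0.595) and cholesterol synthesis (median 0.19, adjusted p = 0.00451, 0.645). Adjusted over the list alone, 6 of 28 complement and coagulation and 3 of 22 acute phase genes passed downward, and 3 immediate early genes passed upward and 1 downward. The number of lists was 7 without HI-PU replicate 1, 9 with the scan day as a block, 6 with quantile normalization and 20 with normexp background correction.

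In all 5 features separated AA from HH cows (5758 at an unadjusted p under 0.05). Leaving out 1 cow gave 3 without HI-CR replicate 1 or 4 and 2 without HI-PU replicate 1, 3 or 4. It gave 1 without LO-PU replicate 1, 2 or 3, HI-CR or HI-PU replicate 2 or LO-CR replicate 3. It gave 12 and 27 without LO-CR and LO-PU replicate 4. AA cows were scanned on scan days 2 and 4, HH on 1 and 3, AH on 1 and 4 and HA on 2 and 3, so no day held both breeds or crosses. The split was 0 higher and 2 lower with normexp background correction, 3 higher and 8 lower with quantile normalization, 18 higher and 45 lower with a higher floor and 4 higher and 0 lower with the deposited values. With the scan day as a block the count was 2 and IGFLR1 differed by -3.37 (adjusted p = 0.0483). With 3 cows assigned as in the deposited values IGFLR1 differed by -2.71 (adjusted p = 0.254), with those values themselves by -2.69 (adjusted p = 0.409), and without the 4 cows of the other protocol by -3.54 (adjusted p = 0.146). The array held 1 probe of IGFLR1. Between AH and HA cows 0 features passed in limma (2652 at an unadjusted p under 0.05). The smallest p values were those of CYP2C89 (1.56 ± 0.24) and PTX3 (-2.30 ± 0.34), both with adjusted p = 0.125. Next were CPEB1 (2.28 ± 0.44), DHX36 (1.07 ± 0.20), hmm239033 (1.30 ± 0.25) and LRRC2 (-1.34 ± 0.26), and then MS4A18 (-1.19 ± 0.24), SALL1 (-1.11 ± 0.23), FKBP5 (-1.40 ± 0.29) and RMND1 (0.96 ± 0.20), each with adjusted p = 0.298. The other probes of CPEB1, DHX36 and RMND1 gave 0.047 (adjusted p = 0.987), 0.013 (adjusted p = 0.995) and -0.40 (adjusted p = 0.715). Leaving out 1 cow gave 1 without HI-PU replicate 2 or 4, HI-CR replicate 3 or LO-PU replicate 4.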

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

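The tests of explanations and other splits of the cows were chosen after the results they bear on were seen. Only the correlation with a further list of muscle genes was written down beforehand.

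The first pattern is the number of genes that moved between days -165 and -15, which is also a step from one array position to the next. The other extraction protocol was constant within cows, so it alone gives no change over days (1021 features without its 4 cows). A smaller share of hepatocytes, which would raise the markers of every other cell type, is argued against by neutrophil markers that changed by -0.744 relative to T and NK cell markers (14 of 16 cows below 0). Array position stays open: 8 spike-in transcripts differed by a mean of 0.277 (SD between spike-ins 0.0642) over this step, with SDs of 0.508 to 1.18 over 16 slides and rises in 8 to 11 of them, beside a median absolute change of 0.628 in called genes. A change of the liver with gestation, which the design names, could not be separated from position.

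The next pattern is the muscle transcripts that stood high in single liver biopsies, with scores of 6.91 and 6.16 in HI-CR replicates 1 and 4 at day +15, 6.19 in HI-CR replicate 3 at day -15 and 5.68 in HI-PU replicate 4 at day +15 (MYL2 and ACTA1 reached 7.59 and 7.49, beside medians of -3.77 and -2.18, and 0 of the 12 markers are in another list). A lasting property of the cow is argued against, since the share of variance between cows was -0.0471. Muscle tissue taken with the biopsy is a candidate source: a further list of 19 muscle genes followed the markers over 16 cow means (r = 0.852, permutation p = 2.00e-05, rho = 0.779, permutation p = 6.20e-04). Without the 2 cows farthest from the median r was 0.617 (permutation p = 0.0207), and with ANKRD1, added later (20 genes), r was 0.857 (permutation p = 1e-05, the smallest that the permutations can give). Herbage allowance stays open, at exact p = 0.0114 for HI against LO cows and 0.423 adjusted over 37 lists.

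The last pattern is the low IGFLR1 signal in AA cows. Scan day is argued against as the whole cause, since crossbred cows of scan days 2 and 4 differed from those of 1 and 3 by only -0.304. Slide assignment is argued against as the whole cause. The undisputed AA cows (replicates 2, other protocol) lay below -2.50 and HH cows, all undisputed, above 0.016. By 6 genes separating these cows the right record stays open. LO-PU replicate 4 (AA) lay 0.262 of the way to AA by the deposited values and 0.440 by its scanner files. The slide of HI-PU replicate 4, by those values a crossbred cow, lay at 0.622. The scanner files put 2 of 3 disputed slides on the side of their breed and the deposited values 0. A sequence variant under the 1 probe could not be tested by another. Crosses would share it, but AH (0.857) and HA cows (0.614) lay near HH cows (0.639). A difference between the breeds, which the design names, stays open.

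Single samples that stood apart from the others of their group were found in 30 of 283 groups tested, where chance gives about 1 in 20 groups (14.2). The share of probes well above background was 61.8% in HI-CR day +60 replicate 2 (next 72.9%) and 48.3% in LO-PU day -15 replicate 2 (next 77.5%). The 75th percentile signal was 1075 in HI-PU day -165 replicate 1 (next 1359). The muscle score was 1.33 in HI-PU day -15 replicate 3 (next -1.42) and 2.77 in LO-PU day -165 replicate 4 (next -0.95). The rest are log2 levels, with the nearest other cow in parentheses. In the means over time they were SLC16A8 -6.64 in HI-PU replicate 4 (next -5.91), B4GALNT1 -5.94 in LO-CR replicate 4 (next -4.99), SLC43A3 -2.70 in LO-PU replicate 3 (next -2.30) and MS4A18 -5.50 in LO-CR replicate 1 (next -6.22). For allowance they were FMNL3 -6.24 in HI-CR replicate 3 (next -6.52), IQCG -4.77 in LO-CR replicate 2 (next -4.08) and TRGC6 -0.054 in HI-PU replicate 1 (next -0.85) at day -165, and GNPDA1 -1.08 in HI-CR replicate 4 (next -2.24), SLC7A9 -1.75 in LO-CR replicate 2 (next -0.96) and TM7SF2 1.57 in LO-PU replicate 2 (next 2.24) at day -15. On day +15 they were C11H2orf50 -4.75 in HI-PU replicate 2 (next -5.89), IL19 -4.73 in HI-PU replicate 2 (next -5.77), MYBPC1 -5.49 in LO-PU replicate 2 (next -6.29) and SMAD5 -4.94 in HI-PU replicate 2 (next -5.89), and on day +60 SP4 -5.93 in HI-CR replicate 3 (next -6.40) and STXBP5L -6.22 in HI-CR replicate 3 (next -6.55). For genotype class they were AVPR1B -3.60 in LO-PU replicate 2 (next -4.31), HOMER3 -5.40 in LO-CR replicate 1 (next -6.08) and PI15 -4.94 in LO-CR replicate 2 (next -5.89) at day -165, and SAXO1 -6.31 in HI-CR replicate 2 (next -6.64) at day -15. At day +15 there was KCNK10 -5.75 in HI-CR replicate 3 (next -6.47), and at day +60 LRR1 -1.67 in HI-CR replicate 2 (next -2.86), LRR1 -0.46 in HI-PU replicate 4 (next -1.72), QTRT2 -3.0 in LO-PU replicate 2 (next -4.17) and RRS1 -0.27 in HI-CR replicate 4 (next -1.72).

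Other splits of the cows, 100 for each comparison (35 between breeds or crosses) with the real one included, bear on chance. For the time comparisons the real labels alone gave as many features (1 of 100 each, the least possible). Between days -165 and -15 the real count was 3343 and the highest other 1132, across calving 8 and 1, between days +15 and +60 286 and 3, and for lactation against gestation 5187 and 1738. For AA against HH cows 1 of 35 splits, the real one, gave 5 features, and the highest other gave 3. Where the real count was 0, all 100 splits must give as many (35 of 35 for AH against HA, highest other 20), which says nothing about chance. Splits of HI and LO cows gave up to 972 features in the means over time, 2354, 29, 164 and 1 on days -165, -15, +15 and +60, and 619 in the interaction with time. Except on day +60 the highest put 0, 4, 3 and 1 cows of scan days 1, 2, 3 and 4 into 1 group. This, perhaps 1 split, points to structure by scan day or protocol. With the scan day as a block HI against LO had 0 features in the means over time (1153 at an unadjusted p under 0.05 in limma). Splits of crossbred and purebred cows gave up to 0 features in the means, 2, 1, 4 and 26 on the days, 5 in the interaction with time and 1 in that of allowance with genotype class.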

How the results depend on the processing

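Leaving out cows or arrays, the deposited slide assignment, the outlier spots and the higher floor were chosen after seeing the data, except leaving out each cow in turn. Of 489 named pairs of gene and comparison 272 passed the threshold, and 74 of these kept their side and direction under every alternative run, while 198 lost the threshold under at least 1 and 1 reversed. Of those that did not pass, 26 passed under at least 1 alternative and 60 reversed under at least 1. The cause was not tested for the changes below, except that fewer cows or features leave less to test. Signal over background limits dim genes: 20.6% of spot values lay at the floor, where normexp and a higher floor give other values. The median of all features moved with the deposited values, which were not scaled between arrays, to 0.23, 0.20 and 0.30 for HI against LO on days -165, -15 and +60 and -0.25 for CR against PU on day +60.

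The replicate number, which is the scan day, was also fitted as a replicate block. Same-numbered cows of different treatments on 1 day correlated at a mean of 0.152 (96 pairs, 55 over 0.1, lowest -0.356), those of different numbers at -0.0495 (288 pairs), and arrays of 1 cow on different days at 0.352 (96 pairs, 93 over 0.1), so same-numbered cows share part of their deviations, but not every pair does, and the number was not used to pair cows. With that block 0 features passed for HI against LO and CR against PU in the means and on each day, and 2 and not 5 did for AA against HH. Without the cow as a block (no replicate block) counts were 1470 and not 3343 between days -165 and -15, 4 and not 8 across calving, 51 and not 286 between days +15 and +60 and 2191 and not 5187 for lactation against gestation. With the cow as a random block they were 15 across calving, 4 for the interaction of allowance and class, 112 for AA against HH and 30 and not 0 for AH against HA.

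Counts that moved by more than 1.5 times follow, with the reported count after each. With normexp background correction they were 1598 between days -165 and -15 (3343), 2 across calving (8), 146 between days +15 and +60 (286), 2105 for lactation against gestation (5187) and 2 for AA against HH (5). With quantile normalization they were 5 across calving (8), 11 for AA against HH (5) and 1 for AH against HA (0). With no filter on dim probes they were 4 across calving (8), 1 for HI against LO at day -165 (0) and 1 for CR against PU at day -165 (0). With a minimum of 60 arrays they were 11 for AA against HH (5). With the deposited values they were 1700 between days -165 and -15 (3343), 4 across calving (8) and 3277 for lactation against gestation (5187). With the deposited slide assignment they were 24 across calving (8), 1 for CR against PU at day +15 (0) and 3 for AA against HH (5). With the higher floor they were 63 for AA against HH (5). Without the 3 cows of conflicting records they were 123 between days +15 and +60 (286), 2 for AA against HH (5) and 2 for AH against HA (0). Without the 4 cows of the other protocol they were 1021 between days -165 and -15 (3343), 5 across calving (8), 112 between days +15 and +60 (286), 1 for HI against LO at day +15 (0), 0 for AA against HH (5) and 1 for AH against HA (0). Without the 2 arrays of lowest correlation they were 478 between days +15 and +60 (286) and 2 for AH against HA (0). With the scan day as a replicate block and without those 2 arrays they were 1 for HI against LO at day +60 (0) and 1 for AA against HH (5). Of 555 gene list tests camera called 121, but 241 with normexp, 18 with fry and 2 with an estimated correlation. Other totals, and counts of features with outlier spots kept or every probe on its own, lay within 1.5 times of those reported. Lists called on single days moved by more than 1.5 times as follows (reported number in parentheses). With normexp background correction there were, for HI against LO 17 (3) on -15, 26 (5) on +15 and 24 (8) on +60 and for CR against PU 24 (0) on -165, 15 (3) on +15 and 21 (7) on +60. With quantile normalization there were, for HI against LO 6 (3) on -15 and for CR against PU 3 (0) on -165, 5 (3) on +15 and 4 (7) on +60. With the deposited slide assignment there were, for HI against LO 9 (5) on +15 and for CR against PU 2 (0) on -165 and 5 (3) on +15. Without the 3 cows of conflicting records there were, for HI against LO 8 (5) on +15. Without the 4 cows of the other protocol there were, for HI against LO 9 (3) on -15, 3 (5) on +15 and 5 (8) on +60 and for CR against PU 6 (0) on -165, 10 (3) on +15 and 4 (7) on +60. Without the 2 arrays of lowest correlation there were, for HI against LO 7 (3) on -15 and for CR against PU 4 (7) on +60. An array position effect could not be fitted, since position and day coincide.

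Leaving out 1 cow gave, as lowest and highest, 2002 and 4622 features between days -165 and -15, 3 and 34 features across calving, 138 and 445 features between days +15 and +60 and 3623 and 5756 features for lactation against gestation. It gave 0 and 3 for HI against LO in the means, 0 and 2 for CR against PU in the means, 0 and 3 for the interaction of allowance and class, 0 and 3 for HI against LO at day -15, 0 and 1 for CR against PU at day -15, 0 and 1 for HI against LO at day +15, 0 and 1 for CR against PU at day +15, 1 and 27 for AA against HH and 0 and 1 for AH against HA, and 0 elsewhere. The number of gene list tests called was 109 to 136. On days -165, -15, +15 and +60 lists numbered 6 to 13, 1 to 7, 3 to 10 and 7 to 14 for HI against LO and 0 to 6, 4 to 15, 3 to 8 and 3 to 10 for CR against PU.

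The sign turned in the following genes, all of which had not passed except CFB (values are log2 changes). With normexp background correction these were for days -165 to -15 FASN 0.018 and for days +15 to +60 CFB 0.0094, IGFBP1 0.029, IGFBP2 0.0071 and PCK1 0.010. Besides they were for lactation against gestation IGFBP2 0.042 and for HI against LO ADAMTS10 0.21, C11H2orf50 0.12, DCDC2B 0.14 and SLC16A8 0.088. In addition they were for CR against PU SSTR5 0.015 and for CR against PU at day -165 AVPR1B 0.55, GPR141 0.59, HOMER3 0.60, LY6G6E 0.041, MFGE8 0.48, PI15 0.48, PLEKHG2 0.57 and hmm4226 0.48. Also they were for HI against LO at day +15 C11H2orf50 0.26, CTNND2 0.093, IL19 0.22 and SMAD5 0.30 and for HI against LO at day +60 C11H2orf50 0.067, LIPE 0.16, PDGFC 0.091, PTX3 0.17, SP4 0.21 and STXBP5L 0.17. With quantile normalization these were for days -165 to -15 IGFBP3 -0.042 and for days +15 to +60 IGFBP1 0.0077, IGFBP2 0.045, IGFBP3 0.016, PCK1 0.036 and PPARA -0.0066. Likewise they were for lactation against gestation IGFBP2 0.10 and SAA3 0.017. With the deposited values these were for days -165 to -15 IGFBP3 -0.030 and INSIG1 -0.027 and for days +15 to +60 MTTP -0.12, SOCS2 -0.19 and TAT -0.075. Besides they were for lactation against gestation HP -0.11, PC -0.014, PPARGC1A -0.036 and TAT -0.12. With the deposited slide assignment these were for CR against PU at day +15 DNAAF11 0.089. Without the 3 cows of conflicting records these were for days -165 to -15 IGFALS 0.0012, IGFBP3 -0.0042, INSIG1 -0.087, SAA3 -0.092 and SREBF1 0.065 and for days +15 to +60 ALB 0.0047, APOB 0.13, CPS1 0.13, GHR 0.10, IGFBP1 0.13, IGFBP2 0.21, PCK1 0.054, PPARGC1A 0.051, SOCS2 -0.039 and SREBF1 0.027. In addition they were for lactation against gestation HP -0.072, IGFBP2 0.027 and MTTP 0.0021. Without the 4 cows of the other protocol these were for days -165 to -15 CPS1 0.11, IGFALS 0.026 and IGFBP3 -0.014 and for calving MTTP -0.091. Also they were for days +15 to +60 APOB 0.0086, HP -0.0039, IGFBP1 0.13 and SOCS2 -0.016 and for lactation against gestation CYP7A1 -0.064 and SAA3 0.25. Without the 2 arrays of lowest correlation these were for days -165 to -15 FASN 0.093 and IGFALS 0.046 and for calving MTTP -0.035. Likewise they were for days +15 to +60 APOB 0.048, CPS1 0.033, GHR 0.014, IGFBP1 0.10, IGFBP2 0.19 and PCK1 0.049 and for lactation against gestation HP -0.0069 and IGFBP2 0.090. With the mean of the probes of a gene these were for days -165 to -15 FASN 0.0011 and for calving FASN -0.054 and IGFALS -0.037. Besides they were for days +15 to +60 MTTP -0.036 and PPARGC1A 0.11. With outlier spots kept these were for days +15 to +60 SOCS2 -0.044. Leaving out 1 cow turned the sign of genes that had not passed, with ranges CPS1 -0.061 to 0.026, FASN -0.24 to 0.10, IGFALS -0.11 to 0.089, IGFBP3 -0.019 to 0.095, INSIG1 -0.073 to 0.24, SAA3 -0.070 to 0.55, SCD -0.40 to 0.013 and SREBF1 -0.17 to 0.021 for days -165 to -15. Ranges were MTTP -0.068 to 0.078 and SREBF1 -0.16 to 0.045 for calving. Ranges were APOB -0.17 to 0.052, CPS1 -0.24 to 0.032, CYP7A1 -0.010 to 0.42, GHR -0.24 to 0.019, IGFBP1 -0.16 to 0.13, IGFBP2 -0.10 to 0.20, IGFBP3 -0.13 to 0.0095, MTTP -0.020 to 0.13, PCK1 -0.065 to 0.061, PPARA -0.050 to 0.25 and SOCS2 -0.094 to 0.17 for days +15 to +60. Ranges were HP -0.20 to 0.24, IGFBP2 -0.10 to 0.10, SAA3 -0.19 to 0.053 and TAT -0.044 to 0.056 for lactation against gestation.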

Other observations

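All tests here were chosen after the results were seen. Whether the change of each gene list over time differed between herbage allowances was tested on the mean of its members per cow, in 111 tests (37 lists and 3 intervals). Across calving, cholesterol synthesis genes changed by -0.32 ± 0.46 in HI and 0.31 ± 0.45 in LO cows (SD, n = 8 each, exact permutation p = 0.0110, 0.612 adjusted). Genes of fatty acid and triglyceride synthesis changed by -0.12 ± 0.22 in HI and 0.29 ± 0.33 in LO cows (SD, n = 8 each, exact permutation p = 0.00735, 0.612 adjusted) in the same interval. Between days +15 and +60 cholesterol synthesis genes changed by -0.81 ± 0.66 in HI and -0.46 ± 0.63 in LO cows (SD, n = 8 each, exact permutation p = 0.235, 0.995 adjusted), and immediate early genes had exact p = 0.0465 (0.995 adjusted). Of the 111 tests 3 had an unadjusted p under 0.05 and 0 an adjusted p under it, so no difference between allowances is established.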
